A study of Mus musculus with 71 samples.

How the data were processed

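The study followed doxycycline-induced reprogramming of mouse embryonic fibroblasts by ChIP-seq with 7 antibodies. The labels list 71 samples, of which 62 have a peak list and 9 are input libraries that were not analysed here. The fibroblasts received doxycycline at 1 µg/ml and vitamin C at 50 µg/ml to day 15, and the day 18 cells were kept for 3 days without doxycycline, per the labels' protocols. Each group, an antibody at a time point or in the iPSC line, held 1 library.

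Per the submitters' processing notes, the tools were CASAVA 1.4, Bowtie 0.12.7, SAMtools and MACS2 2.1.0, and the build was mm9. The notes used here list no version for SAMtools and no role or order of the tools. The peak threshold and the control library were not given in the sources used here. Each list belongs to a single sample, so peaks were taken as called per library. The 17 Oct4 lists are broad-peak tables and the 45 chromatin lists are BED tables, and the value that the authors gave each peak was used as a score. The score in the deposited files was used to rank or filter peaks and for ratios of median scores within a list, and 1 alternative filtered by the scores of an antibody pooled over its lists. In the Oct4 lists the value of column 9 served. In each of their 1135637 rows column 8 was below column 7 and column 7 below column 9, which is not the usual order of fold, p and q, so the columns were not read as such. The BED scores start at 50. A planned filter on fold enrichment was replaced by one on the pooled median score of the antibody.

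No annotation of mm9 was used here. The gene table supplied was of GRCm38.p6, and the lists reach position 197190834 on chromosome 1, past the last gene of that table, which ends at 195291439. Genes were therefore not assigned, regions are given by 1-based mm9 coordinates, and results planned per gene (promoter windows and lists of genes) were not run. Promoter states were described per merged H3K4me3 region instead, as foreseen for this case.

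Overlap meant a shared length of at least 1 bp. Shares carry 95% Wilson intervals, which cover counting error over peaks only, and neighbouring peaks are not independent. The overlapping list was shifted circularly along each chromosome (seed 11), 100 times unless stated. For day 0 total Oct4 peaks against iPSCs, and for H3K27ac over time at new day 1 peaks with Oct4, 20 shifts were made. The share expected by chance was the mean over the shifts. It takes no account of the peaks that the definition of gained or lost regions leaves out, so a share of these regions under it carries no weight. Gained regions were iPSC peaks without a day 0 peak, and lost regions were day 0 peaks without an iPSC peak. The relation of each share to day was measured by Spearman's rho (main) and Pearson's r with exact two-sided permutation tests over all pairings, with Benjamini-Hochberg adjustment over 12 relations and a threshold of 0.05. Day 0 and the iPSC line define the regions and were left out of the relations. With 1 library per group no test between groups and no p-value across peaks was made. Oct4 sites were merged total Oct4 peaks of days 1 to 18 and iPSCs without a day 0 peak, of which 4 classes were followed and 92152 of 193788 sites fell in none. The named regions are the highest by score, up to 5 per target under the rule that a region be present in both late (or both early) libraries and absent from the others, and up to 5 Oct4 sites per class. The text gives the leading ones.

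The alternatives fixed before the data were examined were an overlap of 50% of the shorter peak, the upper 50% of each list by score, lists of equal length, shares over expectation, Pearson's r, other sets of days, sites found with both antibodies, covered length, lists without day 0 peaks, and day 18 as the end point. Joining H3K27me3 peaks less than 3 kb apart, and leaving out the libraries of days 1 to 15 one at a time, and cutting both Oct4 lists of a day to the length of the shorter, were chosen after the data were seen. Overlap and permutation code was tested. Each tested peak was checked under the overlap rules of 1 bp and of 50%, and none of the 1564 checks differed from a brute-force overlap. Of 1000 simulated unrelated series of 7 days, 4.9% had an exact permutation p at or under 0.05. The values of these series were drawn independently, so the check covers the code and not drift between consecutive days of 1 course. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

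Lists of different length affect these measures. A longer list overlaps more of any set of regions, and a peak missing from a list shows that it was not called there, not that the protein or mark was absent. Lists of equal length were cut by score to the shortest list of their own target, so lists of different targets still differed in length. For Oct4 the day 0 lists of both antibodies and the day 18 Flag list were left out in finding the shortest.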

Results

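The series followed mouse embryonic fibroblasts (MEFs) on their way to induced pluripotent stem cells (iPSCs). The MEFs came from embryos made entirely of an earlier iPSC line, so that each cell carried doxycycline-inducible Oct4, Sox2, Klf4 and Myc, with a Flag tag on Oct4. Oct4 is a POU-domain transcription factor of pluripotent cells. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on days 0, 1, 3, 5, 7, 11, 15 and 18, with doxycycline until day 15 and none for the following 3 days. An established iPSC line was the end point. An anti-Flag antibody measured the exogenous Oct4 at the 8 time points, and an anti-Oct4 antibody measured total Oct4 at the same time points and in the iPSC line. Another 5 antibodies gave H3K4me1, a mark of enhancers and promoter flanks, H3K27ac, a mark of active enhancers and promoters, H3K4me3, a promoter mark, H3K27me3, the mark set by Polycomb repressive complex PRC2, and RNA polymerase II (RNAPII), with 9 libraries each.

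The 62 peak lists analysed came from 62 libraries, 1 for each antibody and time. There were no replicates, so a difference between 2 libraries has no replicate error. The intervals below are 95% Wilson intervals that cover counting error over peaks only. Read depth per library was unknown from these files, so only the lengths of the lists are given. The chromatin lists held between 15374 peaks (H3K27me3, iPSC) and 160419 peaks (H3K4me1, day 18). A total of 4 chromatin lists (H3K4me1 on day 18, and H3K27me3 on days 15 and 18 and in iPSCs) held peaks as narrow as 56 to 75 bp, against a minimum of 201 to 326 bp in the other 41. H3K4me3 lists of days 7 to 18 held 15680 to 20704 peaks, against 31346 to 40939 on days 0 to 5.

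The first comparison asked where exogenous and total Oct4 were bound over time. Uninduced MEFs gave 3231 Flag peaks and 634 total Oct4 peaks, the level of each antibody before induction. Of these total Oct4 peaks 17.5% overlapped the iPSC list (0.994% expected from shifted lists), and of the Flag peaks 25.6% overlapped the day 1 Flag list (3.85% expected). What these day 0 peaks are was not tested. On day 1 the lists held 108237 Flag peaks and 92276 total Oct4 peaks, 33.5 and 145.5 times their day 0 lists. Total Oct4 then stayed between 72304 and 87136 peaks through day 15, and held 41339 on day 18 and 31277 in iPSCs. The Flag list held 72112 peaks on day 15 and 1217 on day 18, after withdrawal of doxycycline. On day 1, 77.2% (76.9 to 77.4) of the Flag peaks overlapped a total Oct4 peak, against 4.29% expected from lists shifted along the chromosomes. The share was 51.2% (50.9 to 51.5) on day 5 and 86.0% (85.7 to 86.2) on day 15. In the other direction, 90.7% (90.5 to 90.9) of total Oct4 peaks overlapped a Flag peak on day 1, 70.1% (69.8 to 70.4) on day 15 and 1.45% (1.34 to 1.57) on day 18. The median over days 1 to 15 was 69.6% of Flag peaks and 79.3% of total Oct4 peaks as deposited. With both lists of a day cut to the length of the shorter, it was 74.6% and 75.3%. The share of total Oct4 peaks with a Flag peak was then 83.3% on day 1, 62.9% on day 5, 73.0% on day 11 and 78.5% on day 15. As deposited it was lower on day 15 than on day 11 (78.3%), so that order depended on list length.

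**Figure D1:**
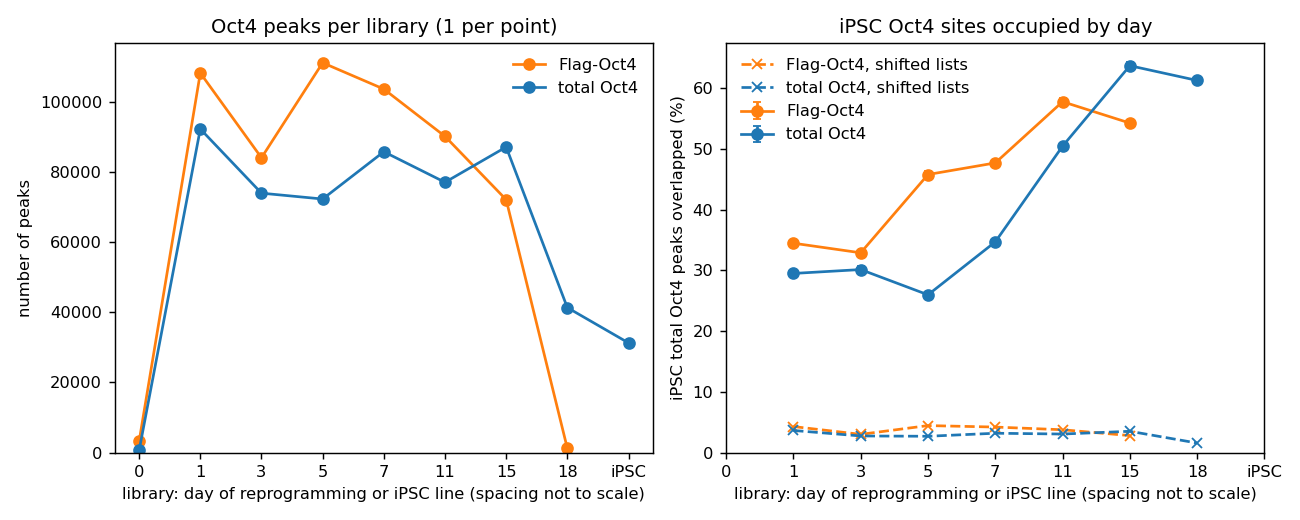
The left panel plots the number of peaks per library for Flag-Oct4 and total Oct4, 1 library per point. The right panel plots the percent of the 31277 iPSC total Oct4 peaks overlapped by each day's list with 95% Wilson intervals, mostly smaller than the points, and crosses give the percent expected from shifted lists. Total Oct4 overlapped 29.5% of the iPSC peaks on day 1 and 61.3% on day 18, while the shifted lists stayed under 5%.

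The second comparison asked when the Oct4 sites of the iPSC line became occupied. Of the 31277 total Oct4 peaks in iPSCs, total Oct4 overlapped 29.5% (29.0 to 30.0) on day 1, 26.0% (25.5 to 26.5) on day 5, 34.7% (34.2 to 35.2) on day 7, 50.5% (49.9 to 51.0) on day 11, 63.7% (63.2 to 64.2) on day 15 and 61.3% (60.7 to 61.8) on day 18. The Flag lists overlapped 34.5% (34.0 to 35.0) of them on day 1, 45.8% on day 5 and 47.7% on day 7. They overlapped 57.8% (57.2 to 58.3) on day 11 and 54.3% (53.7 to 54.8) on day 15. Chance overlap, from shifted lists, was 1.57 to 3.64% for total Oct4 and 2.80 to 4.45% for Flag. Across 7 days the share for total Oct4 gave Spearman's rho 0.86 with day (exact two-sided permutation p = 0.0238, adjusted p = 0.0714 by Benjamini-Hochberg over 12 relations), which did not pass the threshold of 0.05. Pearson's r was 0.95 (exact permutation p = 0.00377, adjusted p = 0.0151), and 0.85 (rho 0.7) without the 2 days farthest from the median day, which are days 15 and 18. For Flag, across the 6 days with doxycycline, rho was 0.89 (exact permutation p = 0.0333, adjusted p = 0.08), also short of the threshold. Pearson's r was 0.89 (exact permutation p = 0.0236, adjusted p = 0.0405), and 0.96 without its 2 farthest days. For Flag these are days 1 and 15, which leaves only 4 days. Both relations passed with lists of equal length and with the share divided by its expectation. At equal length total Oct4 overlapped 15.6% on day 1, 31.6% on day 11, 38.9% on day 15 and 54.5% on day 18. Flag overlapped 29.4%, 38.1%, 41.3%, 53.1% and 54.3% on days 1, 5, 7, 11 and 15. In the upper 50% of each list total Oct4 was at 57.8% on day 15 and 63.9% on day 18, so the order of these 2 days depended on the lists used. Days were single libraries of 1 course, so the test measures order among these libraries.

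The third comparison asked which chromatin the Oct4 sites carried before induction. Total Oct4 peaks merged over days 1 to 18 and iPSCs made 193788 sites, after sites with a day 0 peak were left out. Persistent sites (bound on day 1 and in iPSCs) numbered 9512, transient sites (bound on day 1 and neither on day 18 nor in iPSCs) 75173, late sites (bound in iPSCs and on day 11, 15 or 18, not on days 1 to 7) 10693, and sites bound in iPSCs only 6258. The other 92152 sites (47.6%) belonged to none of the 4 classes. Before induction H3K4me1 lay on 65.1% (64.1 to 66.0) of persistent sites, 34.0% (33.7 to 34.4) of transient sites, 23.5% (22.7 to 24.3) of late sites and 15.3% (14.4 to 16.2) of iPSC-only sites, with 10.0%, 7.98%, 8.19% and 7.17% expected from shifted lists. Day 0 H3K27ac lay on 36.9% (35.9 to 37.8), 15.3% (15.1 to 15.6), 14.9% (14.2 to 15.6) and 10.2% (9.49 to 11.0) of the same classes. With each target's lists cut to its shortest list these were 20.8%, 7.74%, 11.8% and 7.26%, which put late sites above transient sites. Day 0 H3K4me3 covered 32.7%, 5.77%, 13.3% and 7.11% of the classes, and 20.9%, 1.75%, 12.7% and 7.10% at equal lengths, so here transient sites had the lowest share. Day 0 H3K27me3 lay on 1.91% (1.82 to 2.01) of transient sites, below the 4.38% expected, and on 11.3% (10.7 to 11.9) of late sites, above the 4.74% expected. At equal lengths these were 0.718% and 6.74%. Wider sites overlap more by chance, and the median widths of the classes, 1117, 564, 509 and 247.5 bp, followed the same order as the H3K4me1 shares. The shifted expectation includes these widths. Day 0 H3K4me1 was 6.48, 4.27, 2.88 and 2.14 times its expectation in the classes, so their order held beyond chance overlap.

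At transient sites H3K27ac was present on 46.9% (46.5 to 47.2) on day 1, against 15.3% on day 0, and on 28.6% on day 3, 22.8% on day 5, 9.25% on day 7 and 3.76% in iPSCs, where 4.28% was expected. The H3K27ac list held 79093 peaks on day 1 and 42707 on day 3, and the share was 2.03 times its expectation on day 0, 6.34 times on day 1, 6.46 times on day 3, 5.67 times on day 5 and 3.8 times on day 7. The lower share on day 3 was thus not lower over expectation. H3K4me1 at transient sites was present on 43.4% (43.0 to 43.8) on day 3, 17.0% on day 11 and 3.25% on day 18, below the 6.83% expected. At late sites H3K4me1 covered 25.3% (24.5 to 26.1) on day 7, 60.6% (59.7 to 61.6) on day 11 and 84.5% (83.8 to 85.2) in iPSCs. H3K27ac at late sites was present on 9.99% on day 11, 25.2% on day 15, 30.7% on day 18 and 51.2% (50.2 to 52.1) in iPSCs. Of persistent sites, 52.2 to 75.3% carried H3K4me1 in each of the 9 libraries, counted per library without following single sites. The day 18 H3K4me1 list, which gave this 52.2% and the 3.25% at transient sites, was 1 of the 4 with narrow peaks. Differences between single libraries were not tested.

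**Figure D2:**
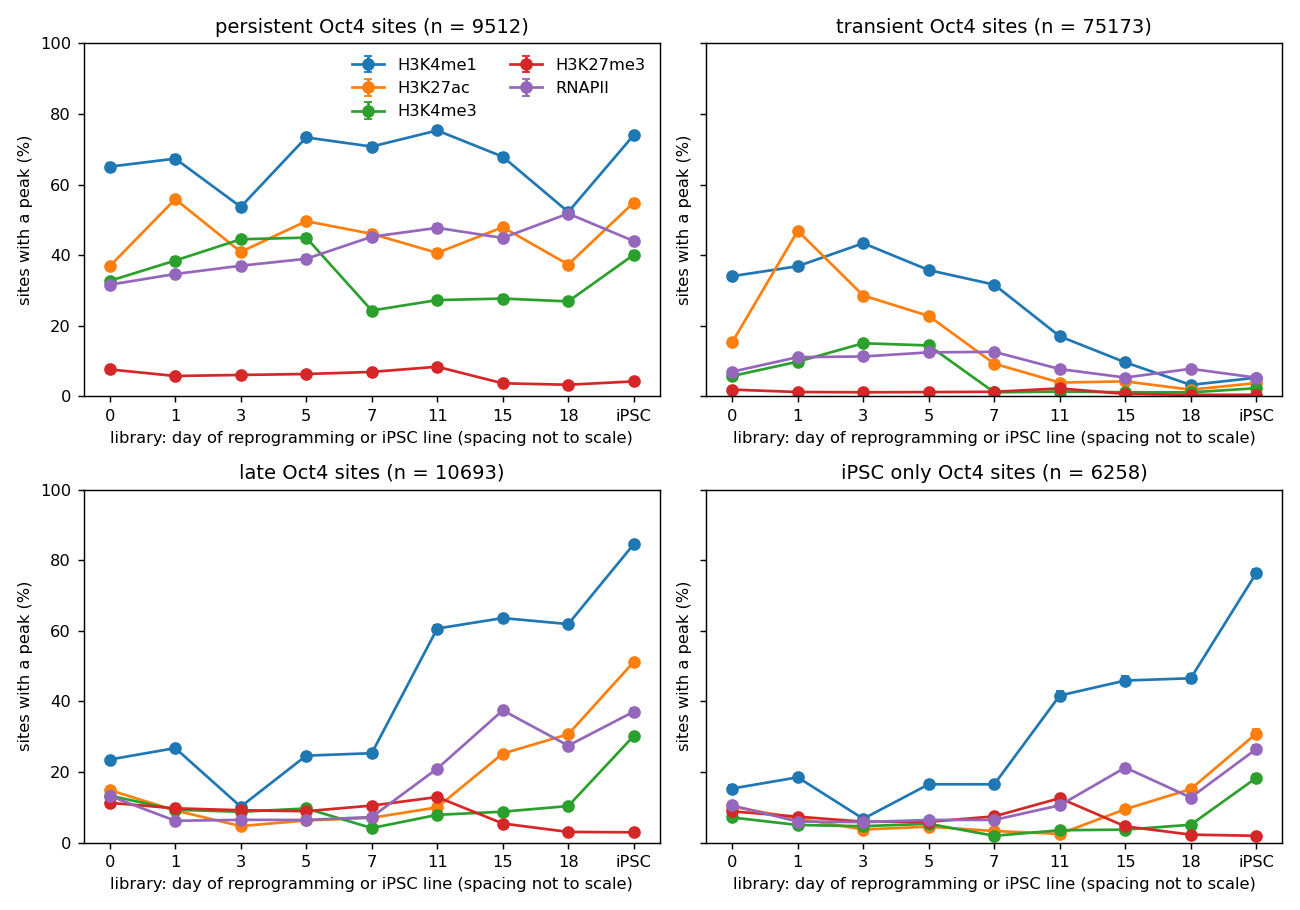
Each panel plots, for 1 class of Oct4 site, the percent of sites that overlapped a peak of each of the 5 chromatin targets in each library, with 95% Wilson intervals smaller than most points. H3K27ac at transient sites was at 46.9% on day 1 and 3.76% in iPSCs, and H3K4me1 at late sites was at 25.3% on day 7 and 60.6% on day 11.

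The sites of highest score in each class had different histories. The persistent site on chromosome 3 from 121848023 to 121848800 (mm9, score 578.1) carried total Oct4 on every day from day 1 and H3K4me1 and H3K27ac on day 18 and in iPSCs only. The persistent site on chromosome 14 from 58351311 to 58352011 (score 487.4) carried H3K4me1 from day 5. Among transient sites, chromosome 8 from 50432782 to 50433884 (score 550.0) was bound on days 1 to 7 and had H3K4me1 on days 0 to 5 and H3K27ac on days 0 and 1, and chromosome 13 from 103642818 to 103643253 (score 545.8) gained H3K27ac on day 1 and lacked it from day 7. Chromosome 5 from 7254413 to 7254882 (score 527.8), a transient site bound from day 1 to day 15, had no peak of any of the 5 targets in any library. The late site on chromosome 14 from 50067340 to 50067817 (score 406.7) had Flag peaks on days 7, 11 and 15, H3K4me1 from day 11 and H3K27ac in iPSCs. The late site of next highest score, on chromosome 9 from 120599620 to 120600052 (score 385.4), had Flag peaks from day 5 to day 15. Late sites were defined by total Oct4 alone. The longer Flag lists overlapped more of all iPSC Oct4 peaks than total Oct4 did on day 5 (45.8% against 26.0%) and day 7 (47.7% against 34.7%). The late site on chromosome 1 from 158913633 to 158914040 (score 314.7) had H3K27me3 on days 0 to 3, 7 and 11 and H3K4me1 from day 11. The iPSC-only site of highest score, chromosome 1 from 91775064 to 91775335 (score 144.8), had H3K4me1 on day 18 and in iPSCs.

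The fourth comparison asked when the chromatin of the iPSC line appeared. Gained regions were iPSC peaks that overlapped no day 0 peak: 58756 for H3K4me1, 19529 for H3K27ac, 10078 for H3K4me3, 4884 for H3K27me3 and 22807 for RNAPII. Gained RNAPII regions rose with day, from 17.5% (17.0 to 18) overlapped on day 1 to 60.7% (60.0 to 61.3) on day 15 and 42.4% (41.8 to 43.0) on day 18 (Spearman's rho 0.96, 7 days, exact two-sided permutation p = 0.00278, adjusted p = 0.0333). Pearson's r was 0.87 (exact permutation p = 0.0105, adjusted p = 0.0315), and 0.95 without the 2 farthest days. Without the library of day 1, 3, 5, 7 or 11 rho was 0.94 and the adjusted exact permutation p was 0.0667 to 0.1, short of the threshold. Over 6 days the smallest exact permutation p is 0.00278 before adjustment, so this does not show that the relation rested on any of these days. Without day 15 or day 18 rho was 1 (adjusted exact permutation p = 0.0167 and 0.0306). The call was also lost in the upper 50% of each list (rho 0.89, adjusted exact permutation p = 0.0819). Gained H3K4me1 regions were overlapped at 10.5% on day 1, 1.76% on day 3, 8.70% on day 5 and 10.5% on day 7, and at 39.3% (38.9 to 39.7) on day 11 and 60.1% (59.7 to 60.4) on day 18. Their rho was 0.79 (exact permutation p = 0.048, adjusted p = 0.0823), and r was 0.95 (exact permutation p = 0.00198, adjusted p = 0.0119), while without the 2 farthest days rho was 0.4 and r 0.82. The day 18 H3K4me1 list was the longest chromatin list, with 160419 peaks, and 1 of the 4 with narrow peaks. With lists cut to the shortest, 32.2%, 41.9% and 44.0% of the 40245 regions then gained were overlapped on days 11, 15 and 18. Gained H3K27ac regions lay between 13.6% and 17.2% on days 1 to 11, at 30.4% (29.7 to 31.0) on day 15 and at 35.8% (35.1 to 36.5) on day 18. Their rho was 0.57 (exact permutation p = 0.2, adjusted p = 0.24) and r was 0.85 (exact permutation p = 0.0187, adjusted p = 0.0377), but -0.13 without the 2 farthest days, so that r rested on those days. The H3K27ac list held 79093 peaks on day 1 and 22491 on day 11. With lists cut to the shortest, the share of the 13445 regions then gained was 10.2%, 14.9%, 18.4%, 24.2% and 28.1% on days 1 to 11 and 52.0% on day 18 (rho 1, adjusted exact permutation p = 0.00238).

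Gained H3K4me3 regions were overlapped at 8.08% (7.56 to 8.62) on day 1 and 21.6% (20.8 to 22.4) on day 18, with 1.78% (1.54 to 2.05) on day 7, whose list was the shortest. Their rho was 0.61 (exact permutation p = 0.167, adjusted p = 0.222) and r was 0.63 (exact permutation p = 0.13, adjusted p = 0.156), or -0.06 without the 2 farthest days. With lists cut to the shortest, 25.0% of the 1946 regions then gained were overlapped on day 7 and 61.1% on day 18 (rho 1, adjusted exact permutation p = 0.00238), while the upper 50% of each list gave rho -0.29 (adjusted exact permutation p = 0.556). Gained H3K27me3 regions were overlapped at 9.64% (8.85 to 10.5) on day 1, 62.4% (61.0 to 63.7) on day 11 and 42.7% (41.3 to 44.0) on day 18. Their rho was 0.68 (exact permutation p = 0.11, adjusted p = 0.164) and r was 0.66 (exact permutation p = 0.103, adjusted p = 0.138), or 0.98 without the 2 farthest days. The narrow-peaked H3K27me3 lists of days 15 and 18 came after the 5 wider lists of days 1 to 11, over which the share was 9.64%, 29.0%, 36.7%, 46.5% and 62.4%. The r of 0.98 above is over these same 5 days, with rho 1 (adjusted exact permutation p = 0.0667), which is fewer days than a correlation should rest on. With lists cut to the shortest, the share of the 6158 regions then gained was 11.2% on day 1, 48.8% on day 11, 27.4% on day 15 and 30.7% on day 18 (rho 0.14, adjusted exact permutation p = 0.854).

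The fifth comparison asked how long the chromatin of the fibroblasts lasted. Lost regions were day 0 peaks that overlapped no iPSC peak. Of 47057 such H3K4me1 regions, 69.4% (69.0 to 69.8) were overlapped on day 1, 73.7% (73.3 to 74.1) on day 5, 41.2% (40.7 to 41.6) on day 11 and 8.60% (8.35 to 8.85) on day 18. The day 18 H3K4me1 list was 1 of the 4 with narrow peaks. With lists cut to the shortest, 63.0% of the 42048 regions then lost were overlapped on day 1, 23.7% on day 15 and 4.78% on day 18. Of 51666 H3K27ac regions, 37.4% (37.0 to 37.8) were still overlapped on day 1, 14.9% (14.6 to 15.2) on day 3 and 4.71% (4.53 to 4.90) on day 18. The H3K27ac lists held 79093 peaks on day 1 and 28578 on day 18. The single day 0 H3K27ac list that defines these regions was overlapped by 41.7% of day 1 peaks and 51.2% of iPSC peaks. With lists cut to the shortest, 30.0% of the 14656 regions then lost were overlapped on day 1, 17.5% on day 3 and 12.5% on day 18 (rho -0.57, adjusted exact permutation p = 0.24). Of 19816 H3K4me3 regions, 20.2% (19.6 to 20.7) were overlapped on day 1 and 0.328% (0.258 to 0.418) on day 7. The day 7 list was the shortest, with 15680 peaks against 31346 on day 1. With lists cut to that length, 51.5% of the 1847 regions then lost were overlapped on day 1 and 19.9% on day 7. The 30390 RNAPII regions lay between 9.94% and 20.9% on all 7 days, and the 45532 H3K27me3 regions were at 51.8% on day 1, 51.0% on day 11 and 12.2% on day 18. The narrow-peaked H3K27me3 lists of days 15 and 18 and of iPSCs covered 44.5, 19.1 and 15.5 Mb, against 141 Mb on day 11. A loss of H3K27me3 after day 11 thus cannot be told apart from this difference between lists.

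With day, lost H3K27ac regions gave rho -0.89 (exact permutation p = 0.0123, adjusted p = 0.0714) and r -0.71 (exact permutation p = 0.0391, adjusted p = 0.0586). Lost H3K4me1 regions gave rho -0.86 (exact permutation p = 0.0238, adjusted p = 0.0714) and r -0.97 (exact permutation p = 0.00139, adjusted p = 0.0119). Lost H3K4me3 regions gave rho -0.79 (exact permutation p = 0.048, adjusted p = 0.0823) and r -0.83 (exact permutation p = 0.0189, adjusted p = 0.0377). Lost H3K27me3 regions gave rho -0.36 (exact permutation p = 0.444, adjusted p = 0.444) and r -0.49 (exact permutation p = 0.269, adjusted p = 0.269). Lost RNAPII regions gave rho 0.54 (exact permutation p = 0.236, adjusted p = 0.257) and r 0.52 (exact permutation p = 0.223, adjusted p = 0.243). None of the 5 passed by rho in the lists as deposited. With lists of equal length H3K4me3 (rho -0.96, adjusted exact permutation p = 0.00556), H3K4me1 (-0.89, p = 0.0185) and H3K27me3 (-0.86, p = 0.0317) passed. With the share divided by its expectation H3K27me3 (rho -0.96, adjusted exact permutation p = 0.0111), H3K4me1 (-0.89, p = 0.0246) and H3K27ac (-0.86, p = 0.0357) passed. For lost RNAPII these 2 alternatives gave rho -0.07 and -0.14. Without the 2 farthest days r was -0.83 for H3K27ac, -0.87 for H3K4me1, -0.91 for H3K4me3, 0.13 for H3K27me3 and 0.13 for RNAPII, and rho was -1, -0.6, -0.9, -0.1 and 0 in the same order. The smallest p that 7 days allow is 0.000397.

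**Figure D3:**
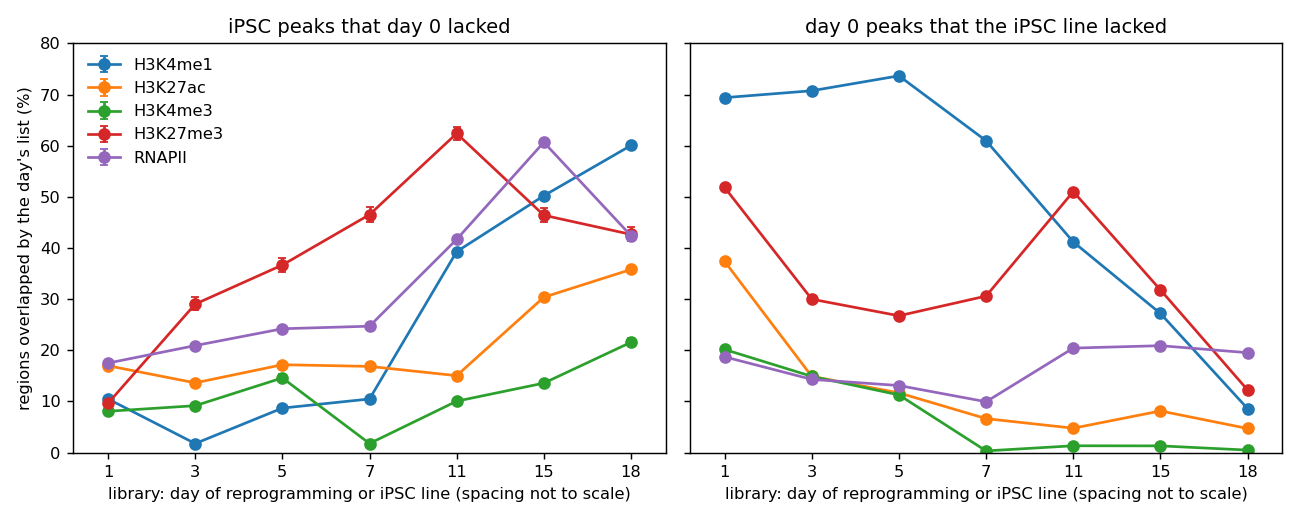
The panels plot, by day and for 5 chromatin targets, the percent of gained regions (left) and lost regions (right) overlapped by that day's list, with 95% Wilson intervals, 1 library per point. Gained H3K4me1 regions went from 10.5% on day 7 to 39.3% on day 11, and lost H3K27ac regions from 37.4% on day 1 to 14.9% on day 3.

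Under the stricter rule that a region be present on day 18 and in iPSCs and absent on days 0 and 1, H3K4me1 had 30925 gained regions, H3K27ac 5389, H3K4me3 1885, H3K27me3 1828 and RNAPII 6618. The gained H3K4me1 region of highest score lay on chromosome 7 from 36146005 to 36153676 (mm9, score 3224) and carried both H3K4me1 and total Oct4 from day 11. The other leading gained H3K4me1 regions had H3K4me1 from day 3 or day 11 and total Oct4 in iPSCs only. The H3K27ac region on chromosome 9 from 95420852 to 95425545 (score 3233) had H3K27me3 on day 0, total Oct4 from day 11 and H3K27ac from day 18. The H3K27ac region on chromosome 8 from 23932359 to 23935826 (score 3233) also had H3K27me3 on day 0 and H3K27ac from day 15. Gained H3K4me3 led with chromosome 17 from 36024010 to 36027341 (score 3208), present from day 11 with no total Oct4 peak in any library. Gained RNAPII led with chromosome 2 from 84645777 to 84649997 (score 3230), with RNAPII and total Oct4 both from day 15. All 5 leading gained H3K27me3 regions carried H3K4me3 and H3K27ac on day 0, among them chromosome 1 from 180457395 to 180462102 (score 1803), where H3K27me3 was present from day 3.

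Present on days 0 and 1 and absent on day 18 and in iPSCs were 29617 H3K4me1, 17953 H3K27ac, 3944 H3K4me3, 19498 H3K27me3 and 3227 RNAPII regions. All 5 leading lost H3K4me1 regions kept the mark until day 15 and carried total Oct4 on days 1 to 15, as did chromosome 7 from 122966594 to 122971814 (score 3192). Of the 5 leading lost H3K27ac regions, 4 had the mark on days 0 and 1 only, among them chromosome 1 from 45444135 to 45453846 (score 3233). The leading lost H3K4me3 region, chromosome 10 from 120318600 to 120321106 (score 3220), kept the mark until day 15. The other leading lost H3K4me3 regions last had it on day 1 or day 3. The leading lost H3K27me3 region, chromosome 2 from 119058561 to 119070939 (score 3100), kept the mark until day 11, and carried total Oct4 from day 11 and H3K27ac, H3K4me3 and RNAPII in iPSCs. The H3K27me3 lists of days 15 and 18 and of iPSCs were the narrow-peaked ones, so its absence there may reflect those lists. The leading lost RNAPII region was 30369 bp wide, on chromosome 1 from 93733749 to 93764117 (score 3100), and was present on days 0 and 1 only. Scores reach a common value of 3100 in many peaks, so the order among those is by width.

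The last comparison asked which H3K4me3 regions also carried H3K27me3, the combination called bivalent. Over 72365 merged H3K4me3 regions, 13.9% (13.5 to 14.2) of the 39558 with H3K4me3 on day 0 also carried H3K27me3. The share was 18.5% (18.1 to 18.9) on day 5, 33.1% (32.4 to 33.9) on day 7, 37.3% (36.6 to 38.0) on day 11, 25.6% (25.0 to 26.3) on day 18 and 19.9% (19.4 to 20.4) in iPSCs. The number of regions with both marks was 6846 on day 5 and 4871 on day 7, while the number with H3K4me3 was 36943 and 14700. Of the day 0 regions with both marks, 66.0% had both in iPSCs, 26.8% had H3K4me3 only and 5.80% had neither. Of those with H3K27me3 only on day 0, 37.3% had H3K4me3 only in iPSCs and 22.2% had both. Of those with H3K4me3 only, 4.09% had both in iPSCs and 55.9% had neither. With day 18 as the end point, 60.1% of the regions with both marks had both. Of those with H3K27me3 only, 9.60% had H3K4me3 only, 13.8% had both and 53.9% had neither. Of those with H3K4me3 only, 2.89% had both and 64.2% had neither. The H3K27me3 list of iPSCs was the shortest of its target and 1 of the 4 with narrow peaks, so these transitions depend on the end point. The 72365 regions were merged from the H3K4me3 lists of all 9 libraries, iPSCs included. A region without H3K4me3 on day 0 thus had it in another library by definition. The shares that gained H3K4me3 are raised by this choice and are no rate for all day 0 H3K27me3 peaks.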

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

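The comparison of both tests below with earlier days was chosen after their results were seen; the tests themselves were not. The Flag and total Oct4 lists moved in opposite directions between consecutive days 3 times, and these differences were not tested, since each day is 1 library. From day 3 to day 5 the Flag list went from 84065 to 111154 peaks and total Oct4 from 73972 to 72304. From day 5 to day 7 Flag went to 103653 and total Oct4 to 85788.

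From day 11 to day 15 Flag went from 90170 to 72112 peaks and total Oct4 from 77072 to 87136. One explanation is that total Oct4, which includes the endogenous protein, added sites of the iPSC line without Flag. The share of day 15 total Oct4 peaks overlapping the iPSC list was lower without a Flag peak (12.5%) than with one (26.7%), a difference of -14.15 percentage points, but it was below 0 on each of days 1 to 11 too (-18.3 on day 11), so its sign does not decide. Total Oct4 peaks without Flag numbered 16753 on day 11, of which 986 overlapped the iPSC list, and 26092 on day 15, of which 3267 did. With both lists of a day cut to the shorter, 73.0% of total Oct4 peaks had a Flag peak on day 11 and 78.5% on day 15, against 78.3% and 70.1% as deposited. Another explanation is that weak peaks may have dropped out of the shorter Flag list: the median score of day 15 total Oct4 peaks without Flag was 0.558 times that of peaks with Flag, but the ratio was 0.571 to 0.695 on days 1 to 11, so it does not decide either. Both explanations stay open.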

How the results depend on the processing

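The alternatives that join H3K27me3 peaks, cut both Oct4 lists of a day to the shorter, or leave out day 1, 3, 5, 7, 11 or 15 were chosen after the data were seen; the others were planned. Unless a reason is given, the cause of a change was not tested. Of relations over 6 or 7 days, 11 of 17 values on iPSC Oct4 sites kept direction and side of the threshold, 45 of 61 on gained regions and 46 of 61 on lost regions. Those over 4 or 5 days are not counted, since the smallest exact permutation p there is 0.0833 or 0.0167 before adjustment. Promoter windows of 1, 2 and 5 kb and the lists of genes were not run for lack of an mm9 annotation. No paired analysis was possible because each group held 1 library.

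Induced over day 0 Oct4 peaks, median of days 1 to 15, was 30.0 (Flag) and 128.4 (total), 73.2 and 467.3 by pooled score, and 53.2 and 199.7 by covered length. Overlap of Flag and of total peaks was 68.5% and 78.6% at 50% of the shorter peak, 68.2% and 76.8% in the upper 50% of lists, and 74.6% and 75.3% with both lists of a day cut to the shorter. It was 40.7% and 93.7% with each antibody's lists cut to 72112 Flag and 31277 total peaks, which limits the Flag share by construction. These were each antibody's shortest lists apart from both day 0 lists and the day 18 Flag list.

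Of relations with day, those now past the threshold were, with rho and exact permutation adjusted p: at 50% of the shorter peak H3K4me1 gained 0.893 and lost -0.893 (0.0492); at equal lengths total Oct4 0.964 and Flag 1 (0.00556), H3K4me1 gained 0.893 and lost -0.893 (0.0185), H3K27ac and H3K4me3 gained 1 (0.00238), H3K4me3 lost -0.964 (0.00556) and H3K27me3 lost -0.857 (0.0317). Over expectation they were total Oct4 0.893, H3K4me1 gained 0.893 and lost -0.893 (0.0246), Flag 0.943 (0.0286), H3K27ac gained 1 (0.00476) and lost -0.857 (0.0357) and H3K27me3 lost -0.964 (0.0111). By Pearson's r they were total Oct4 0.946, Flag 0.891, H3K4me1 gained 0.954 and lost -0.967, H3K27ac gained 0.849 and H3K4me3 lost -0.835. Leaving out 1 library did so for H3K4me1 gained (1, day 1), H3K4me3 lost (-1, day 7) and H3K27ac lost (-1, day 15). Gained RNAPII no longer passed in the upper 50% of lists (0.893, 0.0819) or without day 1, 3, 5, 7 or 11 (0.943, 0.0667 to 0.1). Without the 2 farthest days its rho was 1 and adjusted exact permutation p 0.0667, over only 5 days, so this is no loss of the relation. Direction changed, without a pass, for gained H3K4me3 in the upper 50% (-0.286), lost RNAPII at equal lengths (-0.0714) and over expectation (-0.143), gained H3K27ac without the 2 farthest days (-0.2), and lost H3K27me3 without day 18 or day 1 (0.0286 each). Lost RNAPII had no direction without the 2 farthest days (0). Joined H3K27me3 peaks gave 0.857 gained and -0.214 lost, the same side of the threshold.

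Day 0 H3K4me1 at persistent, transient, late and iPSC-only sites was 61.8%, 28.7%, 21.8% and 14.0% at 50% of the shorter peak, 49.4%, 25.5%, 14.2% and 12.5% in the upper 50%, and 64.1%, 40.7%, 29.4% and 22.4% at equal lengths; with both antibodies it was 66.6% at persistent and 36.3% at transient sites. H3K27ac was 34.8%, 13.8%, 13.1% and 9.03%, then 23.7%, 12%, 9.71% and 7.62%, then 20.8%, 7.74%, 11.8% and 7.26%, with 15.9% at transient sites by both antibodies. Equal lengths put late above transient sites. Regions with H3K4me3 and H3K27me3 were 18.2% on day 0 and 21.9% in iPSCs in the upper 50%, and 25.6% with day 18 as end point.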

Other observations

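The test of X copy number, the values per target with it and the values by width of peak were chosen after the results were seen. On day 1, 46107 H3K27ac peaks overlapped none of day 0, and total Oct4 lay on 64.4% (64.0 to 64.8) of them, against 48.7% (48.2 to 49.3) of the 32986 present on day 0, with 6.72% and 10.0% expected from shifted lists. Of the 29698 new peaks with Oct4, 52.0% had H3K27ac on day 3, 18.4% on day 7, 8.79% on day 11 and 6.61% (6.33 to 6.90) in iPSCs, where 5.15% was expected. H3K4me1 lay on 53.1% of them already on day 0. New here means new against the single day 0 H3K27ac list, which 41.7% of day 1 and 51.2% of iPSC H3K27ac peaks overlapped.

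Of iPSC Oct4 peaks, 5261 carried H3K4me1 and H3K27ac in iPSCs and neither on days 0 and 1. H3K4me1 came in an earlier library than H3K27ac at 66.7% (65.4 to 68.0) of them, H3K27ac came earlier at 12.7% (11.8 to 13.6), and both came in the same library at 20.6% (19.5 to 21.7). By day 11, 59.9% had had H3K4me1 and 13.1% H3K27ac. The H3K4me1 list of day 11 held 117350 peaks and the H3K27ac list 22491, which bears on this order.

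The Flag list of day 18, 3 days after doxycycline was withdrawn, held 1217 peaks. Of these 37.3% (34.6 to 40.1) were also in the uninduced day 0 list, 49.0% (46.2 to 51.8) in the total Oct4 list of day 18 and 14.1% (12.2 to 16.1) in that of iPSCs. Of the 3231 Flag peaks of day 0, 37.9% (36.2 to 39.5) lay on day 0 H3K4me3, against 3.65% expected.

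Of the 69954 H3K27ac peaks of day 0, 75.5% (75.2 to 75.8) had no H3K27ac peak on day 3. In the other direction, 41.7% of day 1, 40.4% of day 3 and 51.2% of iPSC H3K27ac peaks overlapped the day 0 list. The early lists thus shared less with day 0 than the iPSC list did. Day 0 was 1 library, so part of this loss may reflect that list. If the loss followed binding of Oct4 at the peak on day 1, bound peaks should be absent more often. The value went the other way: 42.0% of bound peaks were absent on day 3 against 86.4% of unbound peaks. The difference, bound minus unbound, averaged -37.02 percentage points over 8 strata of score and day 0 H3K4me3 and was below 0 in each. It was -33.97 to -45.3 over quartiles of width. The test did not set apart peaks that had H3K27ac on day 1. Total Oct4 on day 1 lay on 48.7% of day 1 H3K27ac peaks present on day 0, but on only 17151 of all 69954 day 0 peaks. Binding on day 1 thus went with H3K27ac called that day, so the difference cannot speak to loss after binding. That the shorter day 3 list missed only weak peaks met a value against it. The absent share in the highest quartile of score was 0.619 times that in the lowest (54.1% against 87.5%), with 84.9% and 75.4% between. The median score was 432.6 on day 0 and 176.1 on day 3. A day 3 list weaker throughout would miss strong peaks too, which this ratio cannot tell apart. The depth of the day 3 library was unknown, and the cause of the loss stays open.

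The share of H3K4me1 peaks on chromosome X was 2.36% (2.26 to 2.46) on day 0, 3.35% on day 3 and 3.10% on day 5. It was 1.12% (1.07 to 1.18) on day 15, 0.367% (0.338 to 0.397) on day 18 and 1.10% (1.03 to 1.16) in iPSCs. Fewer copies of X in later cells might lower the share for each target. From day 0 to day 18 the ratio as deposited and with lists of equal length was 1.43 and 1.05 for H3K4me3, 1.05 and 1.06 for RNAPII, 0.775 and 1.21 for H3K27ac, and 0.626 and 0.562 for H3K27me3. From day 1 it was 0.482 and 0.465 for total Oct4 to day 18, and 0.478 and 0.531 for Flag to day 15. The starting days differ, and H3K27ac was at 2.40% on day 0 and 4.15% on day 1. From day 7 to day 11, a span picked after the values were seen, the share fell for all 7 antibodies in both settings. As deposited it went from 4.16% to 1.78% for total Oct4, 3.93% to 3.01% for H3K4me3 and 3.00% to 2.38% for RNAPII. H3K4me3 and RNAPII thus showed no fall from day 0 to day 18. From day 7 to day 18, also picked after the values were seen, both fell as deposited with intervals apart. H3K4me3 went from 3.93% to 3.1% and RNAPII from 3.00% to 2.2%. The starting day thus sets the direction, and these 2 targets do not decide on fewer copies. A rise of either from day 0 to day 18 with intervals apart was set to count against fewer copies. The H3K4me3 intervals of these days overlapped with equal lengths (2.72 to 3.25 and 2.85 to 3.40). The shares of both Oct4 antibodies and of H3K27me3 did fall, so copy number stays open. List length alone met a value against it, since with equal lengths the H3K4me1 ratio was 0.0739. The day 18 H3K4me1 list is 1 of the 4 with narrow peaks, so a different calling of that list may account for its value and was not tested. No biological explanation other than copy number was tested.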
